A study of Mus musculus with 8 samples.

How the data were processed

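Total RNA was profiled from T cells of C57BL/6 male mice, per the labels. Recipients carried tail skin grafts from BDF1 donors, a cross of C57BL/6 and DBA/2. Tolerance had been induced with a transfusion of donor cells and the CD40L antibody MR-1. T cells of the spleen and lymph nodes came from tolerant mice on day 100, early tolerant mice on day 21, untreated rejecting mice on day 7, and naive mice without a graft. They were cultured for 20 to 21 hours with dendritic cells grown from donor bone marrow and sorted into CD69+ and CD69- fractions. The labels' sorting text writes both fractions as CD3+ CD69+, so the fraction of each array was taken from its title. The 4 states and 2 fractions gave 8 groups of 1 array each. How many mice made up a group is not given in the sources used here.

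The arrays were Illumina MouseRef-8 bead arrays read in BeadStudio 3.1.3, per the submitters' processing notes. The deposited table of non-normalized values gives the mean bead intensity of each probe, with no background subtraction stated. Each intensity stands beside a detection p-value of the probe, per the file headers. The deposited series matrix holds a normalized intensity on a linear scale, and its normalization is not given in the sources used here. All 8 of its columns held the same sorted values, which were the means of the sorted non-normalized columns, so the values themselves show quantile normalization without centring. The median of every column was 113.

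The probe identifiers printed in the non-normalized table were out of register with its values. Quantile normalization keeps the order of probes within an array, so each of the 25697 probes could be matched between the tables through its values on the 8 arrays. All 25697 matched one to one, and 20106 of them (78.2%) carried another identifier in the series matrix. The named gene differed for 13429 of 22998 probes named under both (58.4%). With the series matrix identifiers, pairs of probes of the same gene had a median correlation across the arrays of 0.936 (2083 pairs), against 0.827 with the printed identifiers (1643 pairs). The T cell gene Cd3d had a mean signal of 24740 under the series matrix identifiers and 778 under the printed ones, and the liver gene Alb 80.1 and 3162. The series matrix identifiers were therefore used, and the printed identifiers were an alternative chosen after seeing the data. Of the 25697 probes, 23978 had 1 gene symbol, none had several and 1719 had no symbol. Symbols were updated through the Entrez identifiers of the 23962 probes found in the RefSeq gene table. They named 16593 genes.

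Intensities were background-corrected, quantile-normalized and log2-transformed with neqc in limma 3.58.1 (R 4.3.3), with the detection p-values standing in for negative controls and an offset of 16. The offset makes fold changes of dim genes smaller than they were. Each gene was represented by its brightest probe on average. Genes with a detection p under 0.01 on at least 2 of the 8 arrays entered the comparisons, which left 7403 genes. Where a gene was not detected on any array of a group, its fold is given as "at least", computed against the lowest detected signal of each array or the probe's own signal if higher. Medians of lists are also given with such genes at their bound where that changed the value, except the medians between fractions within a state, which come from normalized values alone.

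CD69+ and CD69- fractions were compared with limma's linear model and moderated statistics, 2-sided, with recipient state as a block, which left 3 residual degrees of freedom. The pairing came from the design, since the fractions of a state were sorted from the same culture. It was checked before calls were compared: the deviations of the arrays of a state from their fraction means correlated across genes by 0.273 in naive, 0.296 in tolerant, 0.345 in rejecting and 0.209 in early tolerant mice. P-values were adjusted by the Benjamini-Hochberg method over 7403 genes with a threshold of 0.05. Since the 4 states stand in for replicates, the p-values measure how steady the difference between fractions was over the states, and no replicate of a state exists. In simulated data on the 7403 genes with 200 changed genes per run and 3 runs, the same procedure recovered 52.2% of genes changed 1.5-fold, 97.2% at 2-fold and 99.8% at 4-fold. False calls made up 6.01%, 6.57% and 6.11% of calls. In the real comparison 5423 genes passed, far more than the 200 changed here, and the adjustment depends on that share. The recovery and false shares therefore do not carry over to it.

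A total of 24 gene lists were fixed, and 22 with at least 5 tested genes were compared with all other genes by camera in limma, with a preset correlation of 0.01 and with an estimated correlation. The lists covered T cell activation, effector cytokines, Th2, Th17 and Tfh genes, cytotoxic genes, regulatory T cells, anergy, naive and resting cells, cell cycle, interferon response, glycolysis, ribosome biogenesis, cholesterol synthesis, NF-kB, apoptosis, heat shock and stress, chemokine receptors and homing, pan-T, CD4 and CD8 genes, and markers of dendritic and myeloid, B, NK, erythroid and granulocyte cells. Of the dendritic and myeloid list, 27 genes were tested, of which 2 also stand in the NK cell list; T cells also express some of them, such as Ctss and Lgals3.

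Recipient states were compared within the CD69+ fraction, 1 array against 1, without a test. A fit of state over both fractions together, which would ask another question, was not run. Genes at least 1.5-fold apart and detected in the brighter array were counted, with the same count of CD69- cells beside it. The median of a list was placed among 10000 random lists of the same size matched on mean expression. Members of a random list were drawn independently, so lists whose genes vary together reach extreme percentiles more easily. The percentiles describe these arrays and are no test. Candidate tolerance and rejection genes followed the criteria of the series design, which use a fold of 1.5 and a signal of 500. To see what the criteria give without differences between states, they were applied to 100 simulated sets. Without replicate arrays, the spread of the comparison between fractions includes differences between states, so array noise alone was not measured.

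The named genes were the 12 highest and 12 lowest log2 fold changes between fractions among genes that passed the test with the same sign in 4 states, the 8 highest and 8 lowest per state comparison among genes detected on both arrays, the 10 candidates with the highest ratios, up to 4 members of a list with the largest values, and Cd69, Foxp3, Il2ra, Ctla4, Ifng, Il2 and Gzmb. This rule, the lists, the tests and the alternatives, except those named as later, were chosen before the data were examined. Alternatives were other background corrections and normalizations, the series matrix values, other filters and thresholds, the mean of a gene's probes, a fit without the block, robust moderation with a trend, and leaving out each state. Others, chosen after seeing the data, were the printed identifiers, the candidates without marker genes or without genes lower in rejecting cells, and the fit without the tolerant and early tolerant states. Probes without a symbol were fitted apart and only counted. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.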

Results

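Gene expression was measured on 8 bead arrays of T cells that had met donor dendritic cells in culture. CD69 appears on T cells soon after antigen contact, so sorting on it was meant to enrich cells that had responded to the donor. No array came from a culture without donor dendritic cells, so donor specificity of the CD69+ cells was not tested. A CD69+ and a CD69- array stood for each of 4 recipient states: naive, rejecting on day 7, early tolerant on day 21 and tolerant on day 100. Between 9593 and 10308 probes were detected per array (37.3% to 40.1%), with median signals of 107 to 119. Each CD69+ array was brighter than its CD69- partner before normalization, with mean signals of 1038 and 871 in naive cells. With 1 array per group, the number of arrays limits the precision.

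The first comparison asked which genes set the CD69+ cells apart from the CD69- cells of the same culture. Cd69 itself rose in the CD69+ fraction by 1.41 on the log2 scale (SE 0.10, 4 pairs, adjusted p = 4e-05 in limma). Its signals were 4436 to 7543 in CD69+ and 1903 to 3004 in CD69- cells. Ccr8, a chemokine receptor of Th2 and regulatory T cells, was at least 18.2-fold higher in CD69+ cells (adjusted p = 6.8e-06), since no CD69- array detected it. Csf2, which encodes GM-CSF, rose 30.6-fold (log2 4.94, SE 0.19, adjusted p = 8.97e-06), and Ifng rose 20.8-fold (log2 4.38, SE 0.33, adjusted p = 4.5e-05). Il17f was at least 8.79-fold higher over the 4 states (adjusted p = 0.00212) and at least 105-fold higher in rejecting cells, with a lower bound of 1.94 on the log2 scale without that pair. The chemokine gene Ccl3 rose by 4.50, and the cytokine gene Il3 was at least 6.7-fold higher. Bcat1, an enzyme of branched-chain amino acid breakdown, rose by 5.22 (1.99 on the lowest of its 3 probes) and the lysophospholipid transporter gene Mfsd2a was at least 11.7-fold higher. The replication genes Mcm10 and Tk1 rose by 4.75 and 4.40 (1.47 on another probe of Tk1), the mitotic kinase gene Pbk by 4.40 and Lad1 by 5.26. Lad1, Bcat1, Csf2, Ccl3, Pbk and Tk1 were detected on 1 of the 4 CD69- arrays, and Mcm10 and Ifng on 2, so their differences are partly set by signal below detection.

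The genes that fell most in CD69+ cells included receptors and inhibitors of signalling. Il7r, the receptor for the survival cytokine IL-7, was 14.4-fold lower in the CD69+ fraction (SE 0.16 on the log2 scale, adjusted p = 9.06e-06). Pik3ip1, an inhibitor of PI3 kinase, fell by 4.06 on the log2 scale (SE 0.14, adjusted p = 8.97e-06). Cxcr1, a receptor of neutrophil-attracting chemokines, was at least 20.1-fold lower in CD69+ cells. H2-Ob, a modulator of class II peptide loading, fell by 3.88, Cd7 by 3.67 and Ripor2, an inhibitor of RhoA, by 3.62. The phosphodiesterase gene Pde2a fell by 3.53 and the polarity gene Patj by 3.51. Tdrp was 18.4-fold lower, and Acoxl, Tmem71 and Lypd6b fell by 3.75, 3.71 and 3.67. H2-Ob and Ripor2 were detected on 3 of the 4 CD69+ arrays, Patj on 2, and Acoxl and Cd7 on 1.

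Of 7403 genes tested, 5423 passed the threshold in limma, 2607 higher and 2816 lower in CD69+ cells. At least 1.5-fold changes numbered 2035 higher and 2048 lower. With median scaling in place of quantile normalization the split was 2961 higher and 2374 lower, and the median of all genes moved from -0.04 to 0.10.

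Gene lists described the same contrast, and counts adjusted over the list alone equalled those over all genes unless given. Of 21 activation genes, 17 rose and 1 fell, equally so adjusted over the list alone (median log2 1.85, camera adjusted p = 1.01e-05). It was adjusted p = 0.415 with an estimated correlation. Irf4, a transcription factor of antigen receptor signalling, rose by 4.24, Cd83 by 3.71 and Il2ra, the alpha chain of the IL-2 receptor, by 3.68, while Nfatc1 fell by 1.29. Of 20 effector cytokine genes, 16 rose and 3 fell (median 2.60, or 2.59 with bounds, adjusted p = 0.000296, and adjusted p = 0.415 with an estimated correlation). The genes that fell were Ccl5 by 1.52, Stat4 by 1.07 and Ltb by 0.59. Of 15 Th2, Th17 and Tfh genes, 11 rose and 2 fell (median 1.72, or 0.52 with undetected genes at their bounds, adjusted p = 0.02, and adjusted p = 0.415 with an estimated correlation). Il4 was at least 8.62-fold higher, Ccr6 rose by 3.24, and Bcl6, the transcription factor of follicular helper cells, fell by 3.42.

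Regulatory T cell genes were among those that rose. Of 22 tested, 18 rose and 1 fell, and 19 rose and 1 fell adjusted over the list alone (median 2.06, adjusted p = 2.24e-05, and adjusted p = 0.415 with an estimated correlation). Foxp3, the lineage transcription factor, rose by 2.67 (SE 0.17, adjusted p = 2.3e-05). Ebi3, a subunit of IL-35 and IL-27, rose by 3.73, Swap70 by 3.33 and Tnfrsf9 by 3.08, and the ectoenzyme gene Nt5e fell by 1.23. Ctla4 had a log2 difference of 0.72 (SE 0.28, adjusted p = 0.0536), and passed under 4 of 5 alternative settings, with adjusted p of 0.0223 to 0.0561 over the 5. The Ctla4 difference was not steady over the pairs: 1.77 in rejecting, 0.66 in naive, 0.60 in early tolerant and -0.15 in tolerant mice.

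Proliferation and biosynthesis lists rose together. All 27 cell cycle genes rose (median 2.48, or 2.44 with bounds, adjusted p = 2.23e-10, and adjusted p = 0.415 with an estimated correlation), led by Tk1, the replication licensing gene Cdc6 by 4.29, Uhrf1 by 3.98 and Tyms. Of 18 ribosome biogenesis genes, 17 rose, and 18 adjusted over the list alone (median 1.59, adjusted p = 1.19e-06, and adjusted p = 0.49 with an estimated correlation), among them Nop2 by 2.17 and Nop58 by 1.77. Of 16 cholesterol synthesis genes, 12 rose and none fell (median 0.92, or 0.64 with bounds, adjusted p = 0.000518, and adjusted p = 0.501 with an estimated correlation). Sqle, squalene epoxidase, rose by 2.97 and Cyp51 by 2.59. Of 18 NF-kB genes, 13 rose and 3 fell (median 1.00, adjusted p = 0.00942, and adjusted p = 0.501 with an estimated correlation), with Bcl2a1d at 3.11 and Map3k8 at 2.24. Of 19 heat shock and stress genes, 12 rose and 4 fell (median 0.74, or 0.25 with bounds, adjusted p = 0.021, and adjusted p = 0.415 with an estimated correlation). With median scaling that list's adjusted p was 0.0525, and it was 0.0179 to 0.0361 under the other alternatives with the preset correlation. Asns, asparagine synthetase, rose by 4.24 and the chaperone gene Hspd1 by 2.31, and the stress kinase-like gene Trib3 fell by 1.82 over the states. Its difference was 0.04 in rejecting cells, against -1.82 in naive, -3.18 in tolerant and -2.33 in early tolerant cells.

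Lists of resting cells and of the interferon response fell. Of 24 naive and resting genes, 22 fell and none rose, and 23 fell adjusted over the list alone (median -1.82, adjusted p = 1.47e-07, and adjusted p = 0.415 with an estimated correlation). Besides Tdrp, Pik3ip1 and Il7r, Il6ra fell by 3.33. Of 26 interferon response genes, 18 fell and 3 rose, and 4 rose adjusted over the list alone (median -0.73, or -0.69 with bounds, adjusted p = 0.0112, and adjusted p = 0.713 with an estimated correlation). The antiviral genes Ifit3, Oasl2, Ifit2 and Rsad2 fell by 2.68, 2.22, 2.15 and 1.82. Of 16 pan-T genes, 10 fell and 1 rose (median -0.51, adjusted p = 0.02, and adjusted p = 0.415 with an estimated correlation). Cd28 fell by 1.37, Cd3d by 1.14 and Cd3e by 1.13, and Thy1 rose by 0.72.

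Markers of dendritic and myeloid cells rose in the same contrast as these lists. Of 27 tested, 24 rose and 1 fell (median 1.25, or 1.08 with bounds, adjusted p = 0.000252, and adjusted p = 0.644 with an estimated correlation). The costimulatory genes Cd40 and Cd80 rose by 3.25 and 3.14 (1.09 on another probe of Cd40), Fscn1 by 2.86 and Cd74, the class II invariant chain, by 2.79. The median difference of the list was 2.12 in tolerant, 1.97 in early tolerant, 1.05 in naive and 0.23 in rejecting mice. Which cells of the sort the signals of the lists above came from, among them Ebi3 and Swap70, was not tested.

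The remaining lists did not pass. Cytotoxic genes were split, with 5 of 15 higher and 5 lower (median -0.18, or -0.23 with bounds, adjusted p = 0.786): Klrg1 rose by 1.92, while Klrd1 fell by 2.87, Gzmm by 2.39. Anergy genes were also split, with 7 of 15 higher and 7 lower (median 0.04, adjusted p = 0.738): Cd200 and Cd160 rose by 2.72 and 2.43, and Tob1 fell by 2.76. Of 20 apoptosis genes, 7 rose and 6 fell (median 0.08, adjusted p = 0.764): the survival gene Bcl2l1 rose by 4.35, and the death genes Bbc3 and Bcl2l11 fell by 2.32 and 1.86. The apoptosis list had a median of 0.51 in the rejecting pair and of -0.12 to 0.05 in the others, and its direction turned without the rejecting pair. Of 15 glycolysis genes, 2 rose and 2 fell (median 0.004, mean -0.10, adjusted p = 0.913). That list had medians of -0.23 in naive, -0.52 in tolerant, 0.02 in early tolerant and 1.10 in rejecting pairs, and its direction turned without the rejecting pair and with median scaling. Hk2 rose by 1.60, or 1.00 without the rejecting pair, and Pdk1 and Slc2a3 fell by 2.23 and 1.58. Of 13 chemokine receptor and homing genes, 3 rose and 5 fell (median -0.08, or -0.29 with bounds, mean 0.36, adjusted p = 0.865), Itgb7 by 1.47.

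Lineage lists did not pass either. Of 6 CD8 genes, 1 rose and 3 fell (median -0.99, adjusted p = 0.238), Cd8b1 by 1.74. Of 5 CD4 genes, 1 rose and 1 fell, and 1 rose and none fell adjusted over the list alone (median 0.04, adjusted p = 0.7): Izumo1r rose by 1.20. Of 5 B cell genes, 1 rose and 3 fell (median -0.27, mean 0.03, adjusted p = 0.7), Cd79b by 0.91. Of 9 NK cell genes, 4 rose and 2 fell (median 0.50, or -0.23 with bounds, adjusted p = 0.583): Xcl1 rose by 3.36 and Prf1 fell by 1.80. The erythroid and granulocyte lists had 3 and 4 tested genes, too few for camera: Hba-a1 was at least 1.43-fold lower and Mmp9 rose by 0.83. Of the genes fixed for naming, Gzmb was not detected on any array and Il2 was not analysed here. No list passed with an estimated correlation, against 13 of 22 with the preset value.

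**Figure D1:**
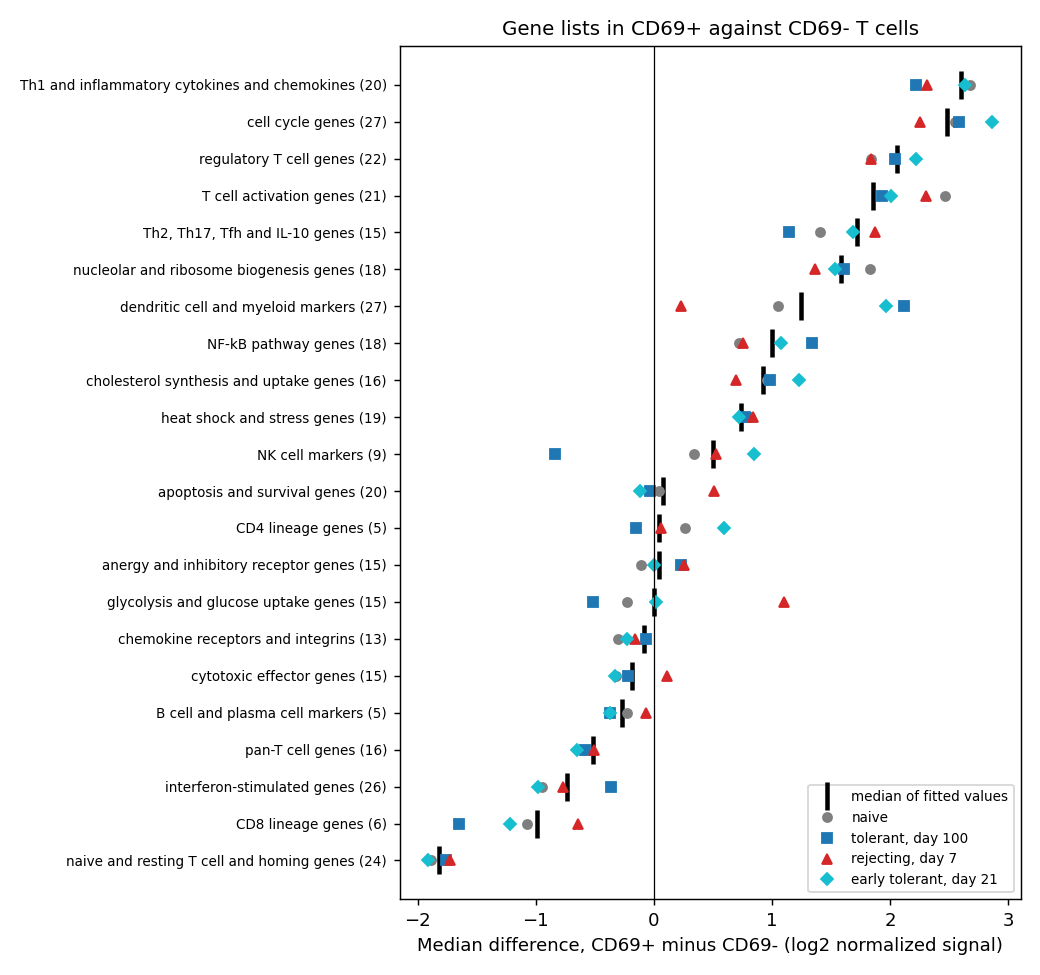
Median log2 difference between CD69+ and CD69- cells of the 22 gene lists, with a point for each recipient state and a bar for the median of the fitted values. Cell cycle genes had a fitted median of 2.48 and naive and resting genes of -1.82, and the dendritic and myeloid list ran from 0.23 in rejecting to 2.12 in tolerant mice.

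The next comparisons asked how CD69+ cells of each recipient state differed from those of naive mice. They had 1 array per side and no replicate, so values are given without a test. In tolerant CD69+ cells the genes furthest above naive were ones known from myeloid cells. Ccl9, a chemokine, was 8.59-fold higher (signal 1959 against 228), and Clec4n, the fungal receptor Dectin-2, 7.12-fold. Lysozyme, Lyz2, was 6.04-fold higher (16130 against 2669), Alox5ap of leukotriene synthesis 6.48-fold, the lysosomal gene Cd63 5.96-fold, Gpnmb 7.18-fold and H2-M2 6.52-fold. H2-Ea, a class II chain whose gene carries a deletion in C57BL/6 mice, was 5.43-fold higher. With the mean of its probes, Gpnmb had a log2 difference of 0.81 in place of 2.84.

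Genes of the Th1 response were lowest in tolerant against naive CD69+ cells. Ifng had a log2 difference of -3.04 (signal 352 against 2896), the chemokine genes Ccl3 and Ccl4 of -2.77 and -2.70, Cxcl9 of -2.18, and Tbx21, the Th1 transcription factor, of -2.10. The cytokine genes Lif and Il24 had differences of -2.24 and -1.99, and the ubiquitin-like gene Ubd of -1.90. The effector cytokine list had a median of -0.73 (percentile 0 of random lists), with 11 of 20 genes at least 1.5-fold lower and 3 higher. The interferon response list had a median of -0.40 (percentile 0; Bst2 -1.28, Gbp2 -1.17) and the CD8 list of -0.71 (percentile 0), or -0.46 with bounds. The NK cell list had a median of -0.87 (percentile 0), or -0.24 with bounds, with 5 of 9 lower and 2 higher. The regulatory T cell list had a median of 0.37 (percentile 99.99; 0.54 in CD69- cells), with 5 of 22 genes at least 1.5-fold higher, 1 lower and 16 within 1.5-fold. Ebi3 was 2.74-fold and Swap70 2.20-fold higher, and Foxp3, within 1.5-fold, had signals of 5140 and 3581. NF-kB genes had a median of 0.33 (percentile 100), and -0.15 in CD69- cells. Beside each of these groups, the dendritic and myeloid list had a median of 1.81 (percentile 100), or 1.65 with bounds, with 24 of 27 markers at least 1.5-fold higher. It was 0.59 in CD69- cells, or 0.51 with bounds. In all, 527 genes were at least 1.5-fold higher and 334 lower, against 201 and 214 in CD69- cells. With median scaling they were 447 and 500, and the median of all genes was -0.11.

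Early tolerant CD69+ cells, taken on day 21, were also compared with naive cells. Ccl17, a dendritic cell chemokine, was 5.51-fold higher, Cd63 5.09-fold, Gpnmb 4.95-fold, Ccl9 4.79-fold, and H2-M2 4.78-fold, and Clec4n had a log2 difference of 2.07. Il4i1, an amino acid oxidase of antigen-presenting cells, was 3.70-fold higher and Apol7c 3.50-fold. Gpnmb had a log2 difference of 0.62 with the mean of its probes. Ccl3 had a log2 difference of -1.87, Ifng of -1.78, Lif of -1.59, Tbx21 of -1.43, Ubd of -1.36, Egln3, an oxygen sensor, of -1.20, Cryba4 of -1.19 and Cysltr1 of -1.16. Ikzf2, the regulatory T cell factor Helios, was 3.38-fold higher. The effector cytokine list had a median of -0.43 (percentile 0, 10 of 20 genes at least 1.5-fold lower), the interferon list of -0.37 (percentile 0; -0.42 in CD69- cells), the heat shock list of -0.36 (-0.35 with bounds) and the glycolysis list of -0.33 (both percentile 0). The regulatory T cell list had a median of 0.21, or -0.11 with median scaling, which shifted all genes down and left the list 0.175 above their median. The dendritic and myeloid list had a median of 1.39 (percentile 100), or 1.09 with bounds, and 0.37 in CD69- cells, or 0.29 with bounds. Counts were 370 higher and 252 lower, against 141 and 173 in CD69- cells. They were 237 and 971 with median scaling, which put the median of all genes at -0.28, and 193 and 76 with quantile normalization without background correction.

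Rejecting CD69+ cells, taken on day 7 from untreated recipients, were next compared with those of naive mice. Il17f was 15.8-fold higher (signal 8413 against 532) and Ifng 6.62-fold (19170 against 2896). Cdkn1a, the cell cycle inhibitor p21, was 9.21-fold higher (5837 against 634), Phlda3, an inhibitor of Akt, 9.97-fold, the kinase gene Plk2 7.04-fold, Gtse1 5.97-fold, Zfp365 6.10-fold and the thiamine transporter gene Slc19a2 5.55-fold. Lyz2 and Lyz1 had log2 differences of -3.16 and -3.00, Ccl17 of -2.53, Igsf9 of -2.05, the class II gene H2-Ab1 of -2.02, H2-Ea of -2.99, Cd40 of -2.00 and the formyl peptide receptor gene Fpr2 of -1.75. Lyz1 and Lyz2 are near-identical copies whose probes were not tested for shared signal, and Lyz1 had -0.96 with the mean of its probes.

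Cytotoxic genes were higher in rejecting than naive CD69+ cells, with a median of 0.71 (percentile 100), 8 of 15 at least 1.5-fold higher and 2 lower, and a median of 0.26 in CD69- cells, or 0.19 with bounds. Among the higher were Klrd1 at 1.47 and Prf1, perforin, at 1.09. T cell genes in general were also higher there: the pan-T list had a median of 0.24 (percentile 99.54). The naive and resting list had 0.21 (percentile 99.53), with 8 of 24 genes at least 1.5-fold higher and 0 lower. The CD8 list had a median of 0.77 (percentile 100) and the apoptosis list of 0.54 (percentile 100), with 10 of 20 higher. Besides Cdkn1a, the latter included the p53 targets Trp53inp1 at 1.99 and Ccng1 at 1.95. Th2, Th17 and Tfh genes had a median of 0.49 (percentile 100), or 0.29 with bounds. Ribosome biogenesis genes had a median of -0.54 (percentile 0; Ncl -0.77), cholesterol synthesis genes of -0.33 (percentile 0.09; Sqle -1.02) and NF-kB genes of -0.24 (percentile 0.14). The effector cytokine list had a median of -0.30 (percentile 0.04), with 5 of 20 at least 1.5-fold higher, Ifng among them, and 4 lower, such as Csf2 at -1.27. The regulatory T cell list had a median of -0.11 (percentile 8.54). Beside these groups, the dendritic and myeloid list had a median of -1.12 (percentile 0), or -0.58 with bounds, with 15 of 27 markers at least 1.5-fold lower, and -0.37 in CD69- cells, or -0.33 with bounds. Counts were 504 higher and 417 lower, against 255 and 323 in CD69- cells. With median scaling they were 403 and 605.

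The direct comparison of rejecting with tolerant CD69+ cells had 1215 genes at least 1.5-fold apart, the most of the 4 state comparisons. Ifng was 54.5-fold higher in rejecting cells and Il17f 52.1-fold. Ccl3 was 13.8-fold higher, Ccl4 9.86-fold, Crip2 9.44-fold, Phlda3 8.45-fold, Cdkn1a 7.64-fold and Zfp365 7.47-fold. Lyz2 had a log2 difference of -5.76, H2-Ea of -5.43, Lyz1 of -5.41, Ccl17 of -4.34, Ccl9 of -4.25, H2-Ab1 of -3.99, H2-Eb1 of -3.70 and the Fc receptor chain gene Fcer1g of -3.43. Lyz1 had -1.85 with the mean of its probes. Cytotoxic genes had a median of 0.69 (percentile 100), CD8 genes of 1.46 (percentile 100), or 1.20 with bounds, NK cell genes of 1.24 (percentile 100), or 0.55 with bounds, activation genes of 0.35 (percentile 99.98) and interferon response genes of 0.25 (percentile 99.95; 0.87 in CD69- cells, or 0.83 with bounds). Nkg7, a cytotoxic granule gene, was 4.71-fold higher. The pan-T list had a median of 0.17 (percentile 97.45). Regulatory T cell genes had a median of -0.31 (percentile 0.01), with Nrp1 at -1.91 and Swap70 at -1.67, while Il10 was at least 6.14-fold higher. The dendritic and myeloid list had a median of -2.92 (percentile 0), or -2.22 with bounds, and -0.68 in CD69- cells. Counts were 573 higher and 642 lower, against 321 and 370 in CD69- cells.

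**Figure D2:**
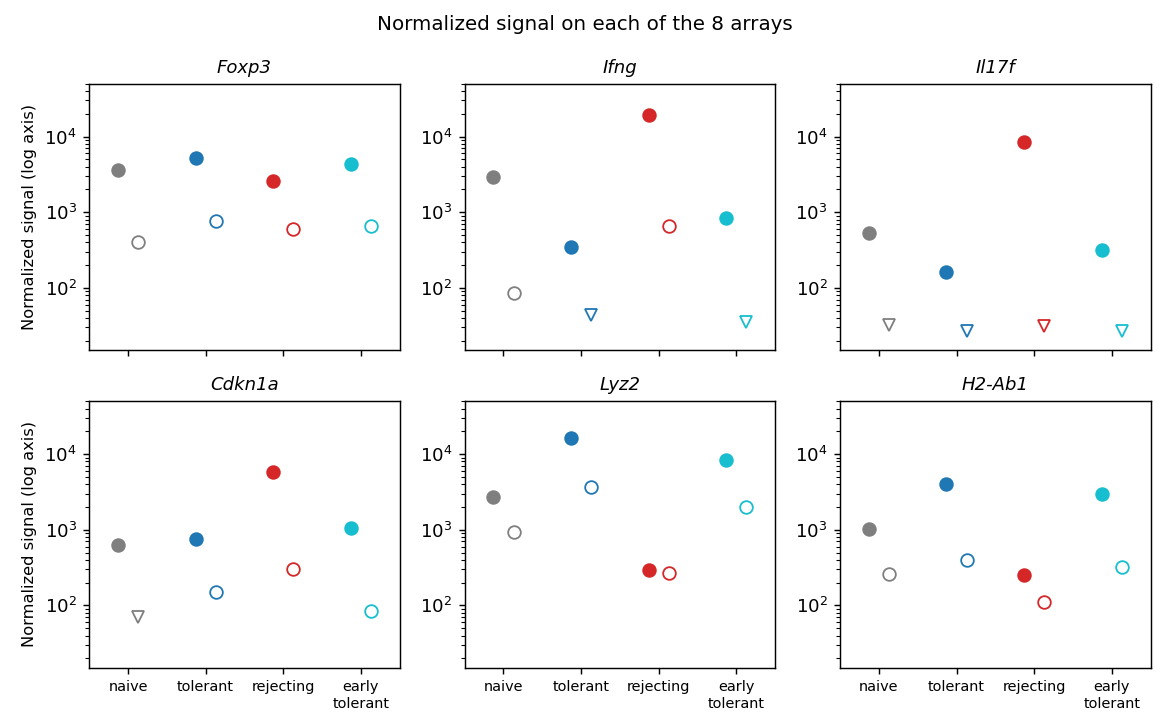
Normalized signal of Foxp3, Ifng, Il17f, Cdkn1a, Lyz2 and H2-Ab1 on the 8 arrays, on a log axis, with filled points for CD69+ arrays, open points for CD69- arrays and triangles where the gene was not detected. Among CD69+ arrays, Ifng ran from 352 in tolerant to 19170 in rejecting cells, and Lyz2 from 298 in rejecting to 16130 in tolerant cells.

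The series design defined candidate tolerance genes as those at least 1.5-fold higher in tolerant CD69+ cells than in naive CD69+ and in tolerant CD69- cells, with a signal of at least 500. These criteria gave 109 genes, while simulated sets with no difference between states gave a mean of 31.2 and at most 44. With tolerant and naive exchanged, 67 genes passed. Those with the highest ratio to naive were Rnase2a, a ribonuclease of eosinophils, at least 11.6-fold, then Ccl9, Gpnmb, Clec4n, H2-M2, Alox5ap, Lyz2, Cd63, H2-Ea and Lyz1 (5.33-fold, or log2 0.89 with the mean of its probes). The dendritic and myeloid list held 15 of the 109, against 0.477 for independent lists among genes with that signal. The latter leaves out the criterion between fractions, where 24 of 27 markers rose, so it is likely too low. Regulatory T cell genes among the candidates were Ebi3, Swap70, Nrp1 (1.77-fold), Ikzf2 (1.72-fold) and Capg (1.52-fold). In CD69+ cells Swap70 had signals of 3253 in tolerant, 2028 in early tolerant, 1480 in naive and 1023 in rejecting mice. Nrp1 had 3368, 2544, 1906 and 896, the same order as Lyz2. Ebi3 and Capg were also highest in tolerant and then early tolerant cells, and Ikzf2 in early tolerant cells. Which cells of the sort these signals came from was not tested. In rejecting CD69+ cells, where the markers were low, 43 of the 109 were at least 1.5-fold below naive, 61 were within 1.5-fold and 5 were above.

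Of 70 genes that met the same criteria in early tolerant cells, 53 were among the 109. Simulated sets, which share the naive array, had a mean of 6.88 and at most 12 in common, and independent lists among genes with that signal in both would share 1.74. Part of the excess may come from the shared naive array, and the value of 1.74 leaves out the criterion between fractions.

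**Figure D3:**
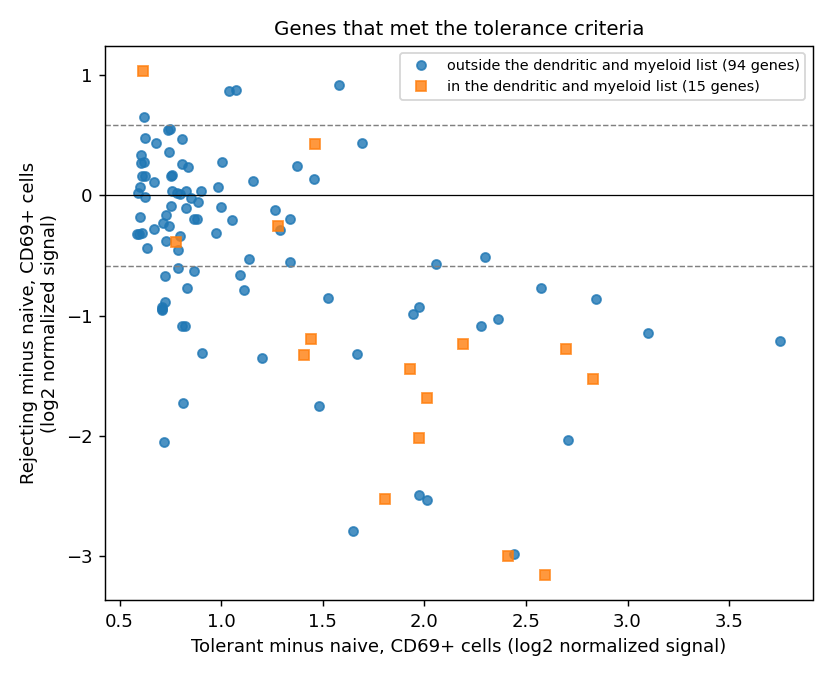
Log2 difference from naive CD69+ cells of the 109 candidate tolerance genes in tolerant cells (horizontal) and rejecting cells (vertical), with 15 genes of the dendritic and myeloid list and 94 others marked apart and dashed lines at 1.5-fold. In rejecting cells 43 candidates lay at least 1.5-fold below naive and 5 at least 1.5-fold above.

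Candidate rejection genes, defined alike against tolerant CD69+ and rejecting CD69- cells, numbered 104, while simulated sets gave a mean of 35.4 and at most 48. Exchanging the states gave 199 genes. Ifng and Il17f had the highest ratios to tolerant cells, and Il17a, which encodes IL-17A, was at least 14.6-fold higher with a signal of 1010. The others named were Ccl3, Ccl4, Crip2, Phlda3, Cdkn1a and Zfp365, with the ratios above, and Il12rb2, a receptor chain for IL-12, at least 7.24-fold higher. None of the 104 was in the dendritic and myeloid list. The criteria ask for genes higher in rejecting than tolerant CD69+ cells, where 0 of 27 tested markers were at least 1.5-fold higher and 24 were lower. The absence therefore says nothing on the source of the candidates.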

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

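Of the tests below, those of H2-Ea and of the candidates outside the marker list in rejecting cells were chosen only after the result was seen. The difference between CD69+ and CD69- cells was first set against chance. Of the 32 ways to split the 8 arrays 4 against 4 that could be fitted with state as a block, 1, the real one, called as many genes. It called 5423 genes and the highest of the others called 0. Of the 8 splits that part all 4 pairs, the 7 other than the real one called 0. The 7 exchange the fractions in some pairs, and the other 24 part fewer pairs. All of them leave the difference between fractions in the residual, so few calls were bound to come from them. They cannot decide on chance, and 8 splits are too few for a share under 0.05.

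Values that stood apart were these. Cd7 was less low in CD69+ cells of rejecting mice (-3.12) than in naive (-3.81), tolerant (-3.81) and early tolerant mice (-3.92), a gap of 0.863 of the range, which made the rejecting value stand away from the others. Cd7 was detected on 1 of the 4 CD69+ arrays, so most of these differences are set by signal near background. Of 50 items tested in this way it alone did so, and chance gives about 1 in 20. The NK cell list was higher in CD69+ cells of naive (0.34), rejecting (0.53) and early tolerant mice (0.85) and lower in tolerant mice (-0.83), a range of 1.69 (0.852 to -0.833) with opposite signs between states that was not tested. These signs rest partly on undetected members, since the list's fitted median over the states turned from 0.50 to -0.23 with bounds. Cryba4 was lower in early tolerant than naive CD69+ cells (-1.19) and higher in CD69- cells (1.03, against a naive signal that was not detected), a difference of -2.22 that was not tested. Of 629 tested probes without a gene name, which no comparison used, 433 passed the threshold between fractions in limma.

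Dendritic and myeloid markers were higher in tolerant than naive CD69+ cells (median log2 1.81) and 15 of the 109 tolerance candidates stood in that list. Array brightness left by normalization was argued against, since pan-T genes had a median of 0.006 (SD 0.247), although it was -0.22 with median scaling. RNA of the donor dendritic cells of the culture is a candidate explanation: H2-Ea, which C57BL/6 recipients do not transcribe and the donor strain does, was higher by a log2 of 2.44 in tolerant cells, as it requires, and its CD69+ signals were 4659 in tolerant, 2845 in early tolerant, 858 in naive and 108 in rejecting mice. H2-Ea was also detected in naive mice, which had no graft, with signals of 858 in CD69+ and 199 in CD69- cells. A sort on CD3 would remove free dendritic cells, and whether it kept ones bound to T cells was not tested. The most abundant markers in tolerant CD69+ cells had signals of 37760 (Lyz1), 16130 (Lyz2) and 13490 (Cst3). Binding of related class II transcripts to the H2-Ea probe was not tested. For the 94 candidates outside the list the dendritic cell explanation stayed open, as did expression by tolerant T cells themselves. Their median in rejecting against naive cells was -0.245 (95% bootstrap interval -0.435 to -0.099), against -1.12 for the markers. A median below 0 is what the dendritic cell explanation requires, but it does not exclude expression by T cells. The interval covers the spread over genes of 1 array per state, not the spread between mice. At least 1.5-fold higher there were 4, chosen after their values were seen (Cercam, Fah, Ifitm2 and Il1r2), 4.26% against 6.59% of all tested genes. Both values use the naive array against which the candidates were chosen.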

How the results depend on the processing

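Of the alternatives below, the printed probe identifiers, the candidates without marker genes or without genes lower in rejecting cells, and the fit without the tolerant and early tolerant states were chosen only after the result was seen. Apart from a threshold of 2-fold, the count of genes that differed between fractions (5423) lay between 4083 (genes at least 1.5-fold apart) and 5765 (no detection filter) under the alternatives fixed or added for it. It was 4853 to 5314 when each state was left out, 4398 without the tolerant and early tolerant states, and 5307 with no block for the pairing of arrays by state. Without the block 13 lists passed, as many as with it. At 2-fold, 1279 genes were higher and 1184 lower. The printed probe identifiers gave 5689, and of 3470 genes called under both sets of identifiers 563 had opposite directions. The 13 list calls held in number when each state was left out, were 12 with median scaling and 0 with an estimated correlation. Quantile normalization without background correction and the series matrix values gave 461 genes in place of 861 for tolerant against naive, 269 in place of 622 for early tolerant, 506 in place of 921 for rejecting against naive and 762 in place of 1215 for rejecting against tolerant. Detection on all 8 arrays, which tests fewer genes, gave 454, 277, 557 and 699, and a threshold of 2-fold, stricter by construction, gave 254, 167, 234 and 478. For early tolerant cells, median scaling gave 1208 and an offset of 50 gave 404. The candidate tolerance genes (109) numbered 67 at a signal of 1000, 48 at 2-fold and 66 without genes lower in rejecting cells, each stricter by construction, and 85 to 163 elsewhere. The candidate rejection genes (104) numbered 68 and 43 at the first pair of these settings and 80 to 133 elsewhere. The printed identifiers gave near counts of other genes: 30 of their 105 tolerance candidates and 43 of their 111 rejection candidates were shared. Except for the stricter settings, the cause was not tested. Of 580 recomputed values of named genes, 518 stayed within their spread or on their side of the threshold, 58 moved, 4 (all Ctla4 between fractions) came to pass and none changed direction. Signals near background limit the folds of dim genes, since the offset and the missing correction in the series matrix both draw them toward 1.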

Other observations

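Tests of the p53 target genes in CD69- cells, reported below, were chosen only after the result was seen, and the p53 target list was written after the highest genes of rejecting cells were known. The CD69- fractions, which stayed without CD69 in the same cultures, also differed between states, each by 1 array and without a test. In rejecting CD69- cells, genes of glycolysis were lower than in naive CD69- cells, with a median log2 of -1.28 (-1.25 with bounds) and 14 of 15 at least 1.5-fold lower. The hexokinase gene Hk2 had a difference of -2.24, the glucose transporter gene Slc2a1 of -2.13, Pfkp of -1.94 and Pfkl of -1.90, while Hif1a had 0.49. The same list had a median of 0.10 in CD69+ cells, or -0.02 with median scaling, which shifted all genes down and left the list 0.076 above their median. Cell cycle genes were higher in rejecting CD69- cells, with a median of 0.41 (0.36 with bounds) and 11 of 27 at least 1.5-fold higher. The dendritic and myeloid list had a median of -0.37 (-0.33 with bounds) there.

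In tolerant CD69- cells, interferon response genes were lower than in naive CD69- cells, with a median of -0.87 and 22 of 26 at least 1.5-fold lower. Oasl2 had a difference of -2.06, the guanylate-binding protein genes Gbp2 and Gbp3 of -1.89 and -1.88, Ifit3 of -1.74, and Isg20 of 0.01. Regulatory T cell genes had a median of 0.54 in the same cells, with 10 of 22 at least 1.5-fold higher and 1 lower, and the dendritic and myeloid list had a median of 0.59 (0.51 with bounds). Against naive CD69- cells, the regulatory T cell list also had a median of 0.28 (0.24 with bounds) in rejecting and -0.055 in early tolerant CD69- cells.

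Several of the genes highest in rejecting against naive CD69+ cells, Cdkn1a, Phlda3, Plk2 and Gtse1, are known p53 targets. Of 12 measured targets not counted as seen when the list was written, 3 were at least 1.5-fold higher. The median of the 12 was 0.27, at percentile 99.06 of matched random lists, which is what a wider p53 response in that array requires. Of the 3, Mdm2 and Ei24 were also candidate rejection genes, as was Tnfrsf10b of the 12. Mdm2, Fas and Tnfrsf10b also stand in the apoptosis list, which was high in the same comparison. The 12 are therefore not independent of the results above, and they do not decide on a wider p53 response. With the 12 targets already seen to be high, which are no independent evidence, 15 of 24 were higher and none lower. A property of all rejecting T cells, CD69- cells included, was not ruled out, although the set as a whole fell short of what it requires, by little more than the spread. The 13 high targets detected in a CD69- fraction had a median of 0.161 there with bounds (SD 0.65), against 1.71 in CD69+ cells. By normalized values without bounds, 3 of them, Cdkn1a, Phlda3 and Gtse1, were at least 1.5-fold higher in both fractions. With bounds, the CD69- folds were at least 3.9 for Cdkn1a, at least 1.3 for Phlda3 and 2.68 for Gtse1. General heat shock or handling stress stayed open, with a median of -0.059 over 19 genes (95% bootstrap interval over the genes -0.352 to 0.24, 2 higher and 3 lower). A difference between single arrays that is not due to the recipient's state cannot be told from one that is.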
